A study of Mus musculus with 4 samples.

How the data were processed

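Total RNA of MC3T3-E1 cells from 4 groups (Control, Miglustat, D-PDMP and D-PPMP, 1 array each) was extracted with an RNeasy kit and labelled with Cy3 by Agilent's one-colour low input protocol, per the labels. The deposited scanner files hold spot intensities from Agilent Feature Extraction 12.1.1.1, whose processed signal is an intensity corrected for background and spatial trend within the array and not normalized between arrays, per the file headers. The series matrix holds log2 values by the authors. Set against the scanner files, each of its columns equals log2 of the processed signal, floored at a signal of 1, minus the array's 75th percentile, not centred on genes and in the direction of the signal. This settles its scale, centring and direction. Its column medians were -4.1, -4, -4 and -3.89. The steps and software behind it are not given in the sources used here.

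For the main values, control spots and spots marked as outliers by the scanner software (70, 67, 66 and 85 spots in Control, Miglustat, D-PDMP and D-PPMP) were left out, log2 of the processed signal was averaged over the spots of a probe, and the array's 75th percentile over its 56605 non-control probes was subtracted. These percentiles were signals of 183, 191, 189 and 189. The scanner files name no genes. Probes were matched by accession without version to a RefSeq table of assembly GRCm38.p6, used for names only, since the array design names build mm9 and no coordinates are given. Of 56605 probes, 32994 (58.3%) matched 22911 genes, of which 7899 had more than 1 probe. The 23611 other probes stayed unnamed. A gene takes the values of its brightest probe over the 4 arrays. Large disagreements with other probes well above background are given for the genes concerned. Well above background on at least 1 array were 15933 genes, and on all 4 arrays 14003.

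With 1 array per group, a difference is the log2 ratio of 2 arrays, called at 2-fold when the gene is well above background on both. No test was made. The measuring error within arrays comes from 300 probes with 10 spots each, of which 288, 290, 289 and 290 were used. The SD of their log2 signals was 0.0365, 0.0315, 0.0295 and 0.0283 for 278 bright probes, and 0.174, 0.189, 0.148 and 0.190 for only 10, 12, 11 and 12 dim ones. The error of a log2 ratio that Agilent's software gives had a median of 0.204. None of these covers differences between cultures. For a gene well above background on only 1 of 2 arrays, the fold is a bound: the brighter level over the higher of the dim array's lowest signal well above background and the dim probe's own signal. All 4 arrays were on 1 slide, in positions 1 to 4 in the order of the groups above, so position and group cannot be told apart.

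Chosen before the data were examined were the 30 gene lists (23 of processes and 7 of other cell types, 741 symbols, of which 736 had a probe). So were the comparisons, the 2-fold rule, the alternatives (but for a spot signal named below) and the rule for named genes. That rule takes, for each inhibitor, the 10 highest and 10 lowest genes against Control with an official-looking symbol, above the median level of probes well above background on the brighter array, likewise 10 and 10 for all 3 inhibitors by the least extreme ratio, and 5 and 5 for each pair of inhibitors. It adds up to 4 members of each list at least 2-fold from Control, or else the 2 most distant, the 5 highest bounds per direction, and 20 fixed genes of the pathway, osteoblasts and references. It gave 203 genes, of which the text names some. Where the median level of genes is named instead, it is that of the genes measured on the arrays compared, a higher limit. A list's members count as measured when well above background on at least 1 of the 2 arrays. The percentile of a list's median comes from 10000 random lists of the same size drawn within 20 bins of mean level, for lists of at least 5 measured members. Random lists were drawn on the main values only, so no random range is known under the other scalings.

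Chance values for comparisons sharing the Control came from 100 simulations of unchanged arrays. Their noise was resampled from the differences between inhibitor arrays divided by the square root of 2, which may hold real differences between inhibitors, and again from the D-PDMP and D-PPMP pair alone. The procedure was tested on simulated data for Miglustat against Control over 14003 genes. Of 50 genes each at a true 1.5-fold, 2-fold, 3-fold and 4-fold, 2%, 38%, 98% and 100% were called, and 78 unchanged genes (0.565%) were called. A list of 30 genes shifted by 0.2 had a median of 0.17 at percentile 100, and 6 of 100 unchanged lists fell outside the middle 95%.

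The alternatives were normexp background correction with an offset of 50, quantile and cyclic loess normalization, the 75th percentile over probes well above background on all 4 arrays, the authors' log2 table, 3 other filters on dim probes, the mean of a gene's probes, and a further condition of 2 times Agilent's error. Normexp was applied to the median spot signal and median background, because the files hold no mean spot signal, on which it had been planned. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used, and R 4.3.3 with limma 3.58.1 for normexp, quantile and cyclic loess normalization. The reference table's other columns were not used here.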

Results

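The data were 4 Agilent one-colour arrays of MC3T3-E1 cells, a mouse osteoblastic line derived from calvaria. The groups were Control, Miglustat at 50 µM, D-PDMP at 10 µM and D-PPMP at 1.0 µM, with 1 array each. All 3 compounds inhibit glucosylceramide synthase, the enzyme that joins glucose to ceramide at the entry of glucosylceramide-based glycosphingolipid synthesis. Cells were treated for 4 days, then replated and kept in culture for another 24 h. Each array gave 59305 spots outside the controls, for 56605 probes. The share of these probes well above background was 57.4% in Control, 60.2% with Miglustat, 60.8% with D-PDMP and 62.4% with D-PPMP. No spot was saturated. Genes well above background numbered 14393, 14856, 14937 and 15271 in the same order. With 1 array per group there is no replicate error, no test and no p-value, and the number of arrays limits the precision. A gene is called higher or lower at a difference of at least 2-fold between arrays on both of which it was well above background. Values given as 3 numbers are log2 ratios over Control with Miglustat, D-PDMP and D-PPMP, in that order. A list's percentile is the place of its median among 10000 random lists of the same size and similar level, as a description of these arrays. The lists of Wnt signalling, of BMP and TGF-beta signalling and of osteoclast-regulating factors hold activators and inhibitors alike. Their medians therefore give no direction of a pathway.

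The target enzyme and its pathway come first, because the series asks which molecules depend on glucosylceramide synthase in osteoblasts. The mRNA of Ugcg, which encodes this enzyme, differed little from Control, at 0.09, 0.08 and 0.00, and its other probes lay between -0.05 and 0.08. B4galt5, a lactosylceramide synthase, was at -0.05, 0.10 and 0.14, and St3gal5, which makes the ganglioside GM3, at 0.12, 0.16 and 0.01. The arrays measured mRNA and say nothing of the enzyme's activity or of lipid levels. In the list of glycosphingolipid synthesis, 19 members were measured, none was 2-fold apart from Control, and the medians were -0.05, -0.01 and 0.02, inside the middle 95% of random lists. The signs of the D-PDMP and D-PPMP medians depend on the scaling. St8sia5, a sialyltransferase of gangliosides, was at -0.21, 0.13 and 0.97. In the list of glycosphingolipid breakdown, 11, 12 and 14 of 16 members were below Control, with medians of -0.08 (percentile 5.07), -0.10 (0.59) and -0.08 (3.1). Examples are Gm2a, the activator protein for ganglioside degradation, at -0.28, -0.62 and -0.50, and Galc, the galactosylceramidase, at -0.43, -0.22 and -0.06. The 34 measured genes of ceramide and sphingolipid metabolism had medians of 0.03, -0.01 and 0.01, inside the random range, the sign for Miglustat and D-PPMP depending on the scaling. Among them were S1pr3, a receptor for sphingosine 1-phosphate, at -0.28, -0.45 and 0.43, and Smpd3, a neutral sphingomyelinase, at 0.34, -0.26 and -0.37.

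Osteoblast genes were examined as a list of 32. Runx2, the master transcription factor of the lineage, was close to Control at -0.05, -0.08 and -0.11, though 1 of its 2 other probes was at 0.25 with Miglustat and 0.23 with D-PPMP, and the other at -0.28 with D-PDMP. Col1a1, the main collagen chain of bone, was at 0.00, -0.08 and -0.13. Sp7, the transcription factor osterix, was at 0.74, 0.02 and -0.44, and Spp1, osteopontin, at -0.66, 0.19 and 0.38. Npnt, the integrin ligand nephronectin, was at 0.63, -1.23 and -1.21. The list medians were 0.00, -0.03 and -0.05 over 25, 25 and 26 measured members, inside the random range, and the sign for Miglustat depends on the scaling. Alpl, the bone alkaline phosphatase, and Ibsp, bone sialoprotein, were not well above background on any array. Bglap, osteocalcin, was well above background only with D-PDMP and D-PPMP, and Tnfsf11, the osteoclast differentiation factor RANKL, only with Miglustat. Neither had a bound of 2-fold or more above Control. The other probe of Tnfsf11, not well above background on any array, was at 0.56, 1.61 and 0.995.

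With Miglustat, the highest genes against Control among those well above background on both arrays and above the median level of probes on the brighter were Dusp1, a phosphatase of MAP kinases, at 1.37, Aspn, the collagen-binding proteoglycan asporin, at 1.28, and Nr4a1, an orphan nuclear receptor, at 1.23. They were 2.59-fold, 2.43-fold and 2.34-fold higher. Sparcl1, a matricellular protein, was at 1.08, Fos, a component of the transcription factor AP-1, at 1.06, and Cyp26b1, which degrades retinoic acid, at 1.01. The glutamate transporter Slc1a6 was at 1.05, the interferon-inducible Ifi27l2a at 1.04, and the natriuretic peptide clearance receptor Npr3 at 0.91. The lowest at such levels was Ramp3, a partner of the calcitonin receptor-like receptor, at -1.54, or 2.91-fold lower. Cox6a2, a muscle subunit of cytochrome c oxidase, was at -1.22, the laminin chain Lama1 at -1.18 and Cdsn, corneodesmosin, at -1.04. Also lower were Chst1, a keratan sulfate sulfotransferase, at -0.98, the potassium channel subunit Kcnmb4 at -0.91, Igfbp5, a binding protein of insulin-like growth factors, at -0.90, the integrin chain Itgb7 at -0.87 and Calr, the chaperone calreticulin, at -0.85.

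Among the lists, immediate early genes stood highest with Miglustat: 23 of 29 members were above Control, 4 of them at least 2-fold (Dusp1, Nr4a1, Fos and Egr3), with a median of 0.25 (percentile 100). BMP and TGF-beta signalling had 25 of 35 members above Control and a median of 0.15 (percentile 100), or 0.13 with members measured on 1 side only at their bound. Its examples are Tgfb2, a TGF-beta ligand, at 0.89 and Bmp4, a bone morphogenetic protein, at 0.62. In Wnt signalling 21 of 28 were above Control, with a median of 0.16 (percentile 100), or 0.09 at the lowest of the other scalings. There Sfrp2, a secreted Wnt modulator, was at 0.50 and Lef1, a transcription factor of the pathway, at -0.55. All 16 measured genes of the smooth muscle and myofibroblast cytoskeleton were above Control, with a median of 0.15 (percentile 100) and Cnn1, calponin, at 0.60. Cell cycle genes had a median of 0.13 (percentile 100), with Prc1, a spindle protein, at 0.37 and Mcm5, a replicative helicase subunit, at -0.31. The extracellular matrix list had a median of 0.04 (99.98), with 28 of 47 members above Control, and p53 targets 0.06 (98.66). Over the other scalings the matrix median lay between 0.02 and 0.08. Below Control lay 20 of 23 genes of cholesterol synthesis and uptake, with a median of -0.18 (percentile 0), Mvd and Dhcr7, enzymes of the pathway, being at -0.62 and -0.32. The interferon list had 19 of 24 members below Control and a median of -0.16 (0.04), with Oasl2 at -0.92 and Gbp3 at -0.51. The hypoxia and glycolysis list had a median of -0.10 (0.14), and the unfolded protein and integrated stress response list -0.07 (1.36), although its member Atf3, a stress transcription factor, was at 0.92. Under cyclic loess these 2 medians were -0.05 and -0.04, inside the random range of the main values.

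In all, 30 genes were at least 2-fold higher and 25 at least 2-fold lower with Miglustat among 14171 measured, and 97.3% lay within 1.5-fold. Under quantile normalization the split was 20 and 26, under cyclic loess 21 and 28, and with normexp 5 and 4. On simulated data for this comparison, 38% of true 2-fold and 98% of true 3-fold differences were called, beside 78 calls among unchanged genes. Of the 14003 genes in that simulation, 29 were observed at least 2-fold higher and 24 lower. The simulated noise was taken from differences between the inhibitors.

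With D-PDMP, Lum, the proteoglycan lumican of collagen fibrils, stood lowest of the genes well above background on both arrays, at -2.87, or 7.31-fold below Control. Dcn, the related proteoglycan decorin, was at -1.66 and Tnn, the matrix protein tenascin-N, at -1.31, or 3.16-fold and 2.49-fold lower. Highest among genes well above background on both arrays and above the median level of probes on the brighter were Egr3, Egr2 and Egr1, immediate early transcription factors, at 1.72, 1.24 and 1.17, with Nr4a1 at 1.23. Errfi1, a feedback inhibitor of the EGF receptor, was at 1.13, Dusp1 at 0.84, Ptgs2, the inducible cyclooxygenase, at 0.83, and Ereg, an EGF receptor ligand, at 0.80. Ifi204, an interferon-inducible gene, was at 0.80 and Fos at 0.76. Lower genes included Igfbp2, a binding protein of insulin-like growth factors, at -1.11, the RNA sensor Tlr7 at -0.94, the matricellular Ccn3 at -0.93, the homeobox gene Tgif2lx1 and the transcriptional coregulator Cited1 at -0.88 each, Igfbp5 at -0.85 and the laminin chain Lama4 at -0.84. Car9, a carbonic anhydrase induced by hypoxia, was at 1.55 on its brightest probe and at -0.24 on its other probe.

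By list, 40 of 47 extracellular matrix genes were below Control with D-PDMP, 3 of them at least 2-fold (Lum, Dcn and Tnn), and the median was -0.14 (percentile 0). Immediate early genes had 26 of 29 members above Control, 4 at least 2-fold, and a median of 0.36 (percentile 100). That median was 0.25 at the lowest of the other scalings. In the unfolded protein and integrated stress response list 30 of 37 members lay below Control, with a median of -0.11 (percentile 0), Cth, which makes cysteine from cystathionine, being at -0.65 and the cystine transporter Slc7a11 at -0.51. Osteoclast-regulating factors had a median of 0.13 (99.93), or 0.08 at the lowest of the other scalings. Of these factors 13 of 18 were above Control, with Ptgs2 at 0.83 and Il11, a cytokine of the IL-6 family, at -0.68. Cholesterol efflux and LXR targets had a median of -0.19 (0.355) over 7 genes, Nr1h3, the receptor LXR alpha, being at -0.87 on its brightest probe. Its other probe, not well above background in Control, lay in the opposite direction at 1.07. The list of glycosphingolipid breakdown was also below the random range, as given above. Medians above it were those of p53 targets at 0.09 (99.2), with the death receptor Fas at 0.53, of cell cycle genes at 0.05 (99.39) and of oxidative stress and NRF2 targets at 0.06 (98.35). Under another scaling the cell cycle and NRF2 medians were 0.04 each at the lowest, inside the random range of the main values. Inside the range were Wnt signalling at 0.01 and cholesterol synthesis at 0.01, both with a sign that depends on the scaling, and BMP and TGF-beta signalling at -0.02. In these lists Sfrp2 was at -0.82, the ligand Wnt4 at -0.60 and Bmp4 at -0.68.

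The count with D-PDMP was 22 genes at least 2-fold higher and 24 lower among 14154 measured, with 97.5% within 1.5-fold. The split was 14 and 36 under quantile normalization, 14 and 38 under cyclic loess, and 4 and 2 with normexp background correction. Of the 14003 genes in the simulation for Miglustat, 22 were observed at least 2-fold higher with D-PDMP and 20 lower. That simulation, with noise from differences between the inhibitors, called 78 unchanged genes.

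With D-PPMP, among genes well above background on both arrays and above the median level of probes on the brighter, Egr3 stood highest at 2.34, or 5.06-fold above Control, followed by the homeobox gene Tlx2 at 1.47, Egr2 and Errfi1 at 1.32 each, and Nr4a1 at 1.20. Of genes well above background on both arrays, Lum was lowest at -2.20, or 4.6-fold below Control. Tnn was at -1.82, Igfbp5 at -1.67, Igfbp2 at -1.40 and Dcn at -1.33. Etv1, a transcription factor of the ETS family, and Arhgap36 were at 1.06 each, Ereg and Egr1 at 0.96 each, and Sgk1, a serum- and glucocorticoid-regulated kinase, at 0.86. Cox6a2 was at -1.24, Cdsn at -1.10, Ccn3 at -0.99, the secreted semaphorin Sema3c at -0.97 and Wfdc13 at -0.96. Inhbb, a subunit of inhibins and activins, was at -1.07. The other probe of Tlx2 was at 0.16, whereas the other probe of Egr3 that was well above background was at 2.67 and that of Tnn at -1.65.

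The extracellular matrix list had 44 of 47 members below Control with D-PPMP, 3 of them at least 2-fold, and a median of -0.25 (percentile 0). In the unfolded protein and integrated stress response list 33 of 37 were below Control, with a median of -0.21 (percentile 0), Slc7a11 at -0.96 and Cth at -0.95. Wnt signalling had 19 of 27 below and a median of -0.12 (0.03), with Sfrp2 at -0.55 and Wnt4 at -0.54. Cholesterol efflux and LXR targets had a median of -0.13 (2.38). With normexp it was -0.08, inside the random range of the main values. Above Control lay 24 of 29 immediate early genes, with 3 at least 2-fold and a median of 0.20 (percentile 100). So did 14 of 18 osteoclast-regulating factors, with a median of 0.24 (percentile 100) and Tnfsf10, the ligand TRAIL, at 0.71. The latter median was 0.15 at the lowest of the other scalings. Cholesterol synthesis and uptake had 15 of 23 above Control and a median of 0.12 (percentile 100), with Insig1, which holds back SREBP processing, at 0.43. Cell cycle genes had a median of 0.09 (percentile 100), with the cyclin Ccne2 at 0.55. The 6 measured metallothionein and metal response genes had a median of 0.25 (99.97), with the zinc exporter Slc30a1 at 0.40. Oxidative stress and NRF2 targets were at 0.06 (99.68) and p53 targets at 0.06 (97.94). With normexp the p53 median was 0.04, inside the random range of the main values.

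At least 2-fold higher were 43 genes and lower 29 among the 14200 measured with D-PPMP, with 96.6% within 1.5-fold. The split turned to 22 and 56 under quantile normalization, 21 and 48 under cyclic loess, and 6 and 8 with normexp, so the side with more genes depends on the scaling. This array also had the highest share of probes well above background. Of the 14003 genes in the simulation for Miglustat, 43 were observed at least 2-fold higher with D-PPMP and 27 lower. That simulation, with noise from differences between the inhibitors, called 78 unchanged genes.

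Other lists had medians inside the random range against Control or too few members. Fatty acid synthesis was at -0.05, -0.02 and -0.02, with Thrsp, a regulator of lipogenesis, at 0.44, 0.81 and 0.55. Lysosome and autophagy genes were at -0.04, 0.01 and -0.04, the D-PDMP sign depending on the scaling. Within that list Gpnmb, a lysosomal and melanosomal glycoprotein also called osteoactivin, was at 0.82, 1.01 and 1.01 and the protease Ctsf at -0.70, -0.95 and -0.69. Inflammatory and NF-kappaB targets were at 0.05, -0.02 and 0.10 (0.04 with bounds), the D-PPMP sign depending on the scaling, and the chemokine Ccl7 was at 0.78, 0.19 and 0.47. With Miglustat, osteoclast-regulating factors were at 0.01, with a sign that depends on the scaling, oxidative stress and NRF2 targets at -0.06 (8.33), metallothionein genes at -0.01 and LXR targets at -0.11 (7.13). Of the regulators of osteoclasts, Tnfrsf11b, the decoy receptor osteoprotegerin, was at -0.08, -0.02 and -0.16, Csf1 at 0.32, 0.14 and 0.20, Il6 at 0.59, 0.44 and -0.18, and the chemokine Ccl2 at 0.79, 0.19 and 0.51. With D-PDMP, metallothionein genes were at 0.11 (94.3) and the cytoskeleton list at -0.05 (3.67). With D-PPMP, BMP and TGF-beta signalling was at -0.02. For D-PDMP and D-PPMP in that order, interferon genes were at 0.03 and 0.05 and hypoxia and glycolysis genes at 0.01 and -0.03, and the cytoskeleton list was at -0.03 with D-PPMP. Of these, the interferon median for D-PDMP, both hypoxia medians and the cytoskeleton median for D-PPMP turn sign under some scaling. The 17 reference genes had medians of -0.05, 0.00 and -0.02, whose signs depend on the scaling in all 3 comparisons. Actb was at 0.02, -0.10 and -0.12 and Gapdh at -0.15, -0.07 and -0.12.

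Markers of other cell types stayed inside the random range against Control. The medians were 0.25, 0.13 and 0.25 for adipocyte, 0.04, -0.02 and -0.09 for chondrocyte, 0.19, -0.07 and 0.04 for skeletal muscle, 0.01, -0.08 and 0.05 for macrophage and blood cell, and -0.01, -0.06 and 0.03 for neural markers. With members measured on 1 side only at their bound, the adipocyte medians with Miglustat and D-PPMP were 0.15 and 0.08. Some of these signs turn with the scaling: adipocyte with D-PDMP and D-PPMP, chondrocyte with Miglustat, skeletal muscle with D-PPMP, and macrophage and neural with Miglustat and D-PPMP. Of 11 endothelial and 7 tendon markers at most 4 were measured, too few for a percentile. Pecam1, an endothelial adhesion molecule, was at 0.23, 0.60 and 0.61, and the tendon list includes Egr1, already given among the immediate early genes. Of 28 lists with a percentile, 11, 9 and 11 lay outside the middle 95%. By chance 1.4 would, if the members of a list varied independently of each other, which was not tested.

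**Figure D1:**
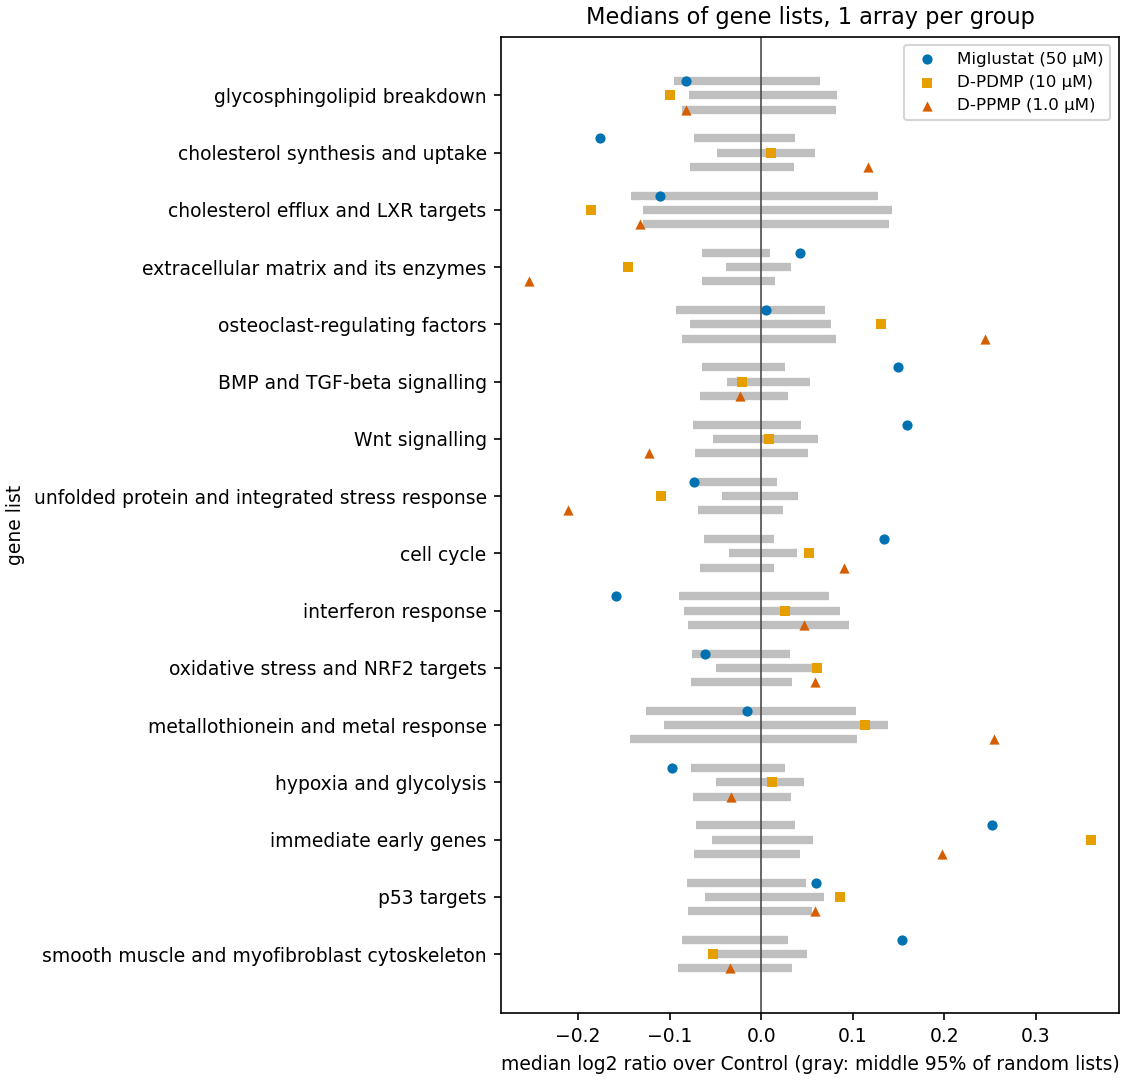
Median log2 ratio over Control (horizontal axis) of the 16 gene lists outside the middle 95% of random lists in at least 1 comparison, 1 array per group; circles are Miglustat, squares D-PDMP and triangles D-PPMP, and gray bars span the middle 95% of random lists. Immediate early genes lie at 0.25, 0.36 and 0.20, and extracellular matrix genes at 0.04, -0.14 and -0.25.

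Genes apart from Control in the same direction with all 3 inhibitors bear on effects the compounds have in common. Nr4a1, at 1.23, 1.23 and 1.20, and Egr3, at 1.14, 1.72 and 2.34, were at least 2-fold higher with each. Egr2 was at 0.75, 1.24 and 1.32, Egr1 at 0.72, 1.17 and 0.96, Ptgs2 at 0.70, 0.83 and 0.55 and Ereg at 0.54, 0.80 and 0.96. Odc1, the rate-limiting enzyme of polyamine synthesis, was at 0.51, 0.58 and 0.51, its dimmer probe at 0.03, 0.17 and 0.17. Igsf10 was at least 2-fold lower with each inhibitor, at -1.42, -1.42 and -1.54, but its other probe, well above background on all 4 arrays, was at -0.01, 0.16 and -0.13. Igfbp5 was at -0.90, -0.85 and -1.67, Cox6a2 at -1.22, -0.71 and -1.24, Cth at -0.82, -0.65 and -0.95, and Vldlr, a lipoprotein receptor, at -0.50, -0.43 and -0.65. Also lower with each were Angptl6 at -0.81, -0.67 and -0.76, Uchl1, a deubiquitinating enzyme, at -0.70, -0.67 and -0.53, and Slpi, a secreted protease inhibitor, at -0.42, -0.72 and -0.58, though the dimmer probe of Slpi was at -0.04, 0.03 and 0.25.

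In all, 4 genes were at least 2-fold higher and 2 lower with all 3 inhibitors. Besides Nr4a1, Egr3 and Igsf10 they were Rgs16 at 2.08, 1.43 and 1.57, Treml2 at 1.09, 1.38 and 1.47, and Gm5800 at -1.34, -1.58 and -1.27, named after their values were seen. By its mean over the 4 arrays, only Nr4a1 of the 6 lay above the median level of genes, a higher limit than the median of probes. Because the 3 comparisons share the Control array, unchanged arrays give such genes too: a mean of 6.91 higher and 6.9 lower in 100 simulations with noise from all inhibitor pairs, and 1.6 and 1.56 with noise from the D-PDMP and D-PPMP pair. Taking Miglustat, D-PDMP or D-PPMP in place of Control as the reference gave 18, 4 and 7 genes in all, beside 6 for Control. Genes well above background only in Control have a lower bound for their fold, the Control level over the higher of the other array's dimmest detected signal and the probe's own signal. By this bound Slco1a4, an organic anion transporter, was at least 6.96-fold, 6.83-fold and 6.8-fold lower, and Pf4, a platelet chemokine, at least 4.04-fold, 3.97-fold and 3.95-fold lower. For each gene the 3 bounds divide the same Control level by each array's dimmest detected signal, so their closeness is given by construction. The same bound made Klk11 at least 5.03-fold higher with Miglustat, the olfactory receptor genes Olfr1277 at least 8.31-fold with D-PDMP and Olfr981 at least 210-fold with D-PPMP, each well above background with that inhibitor and not in Control. Olfr1277 and Olfr981 have no other probe.

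**Figure D2:**
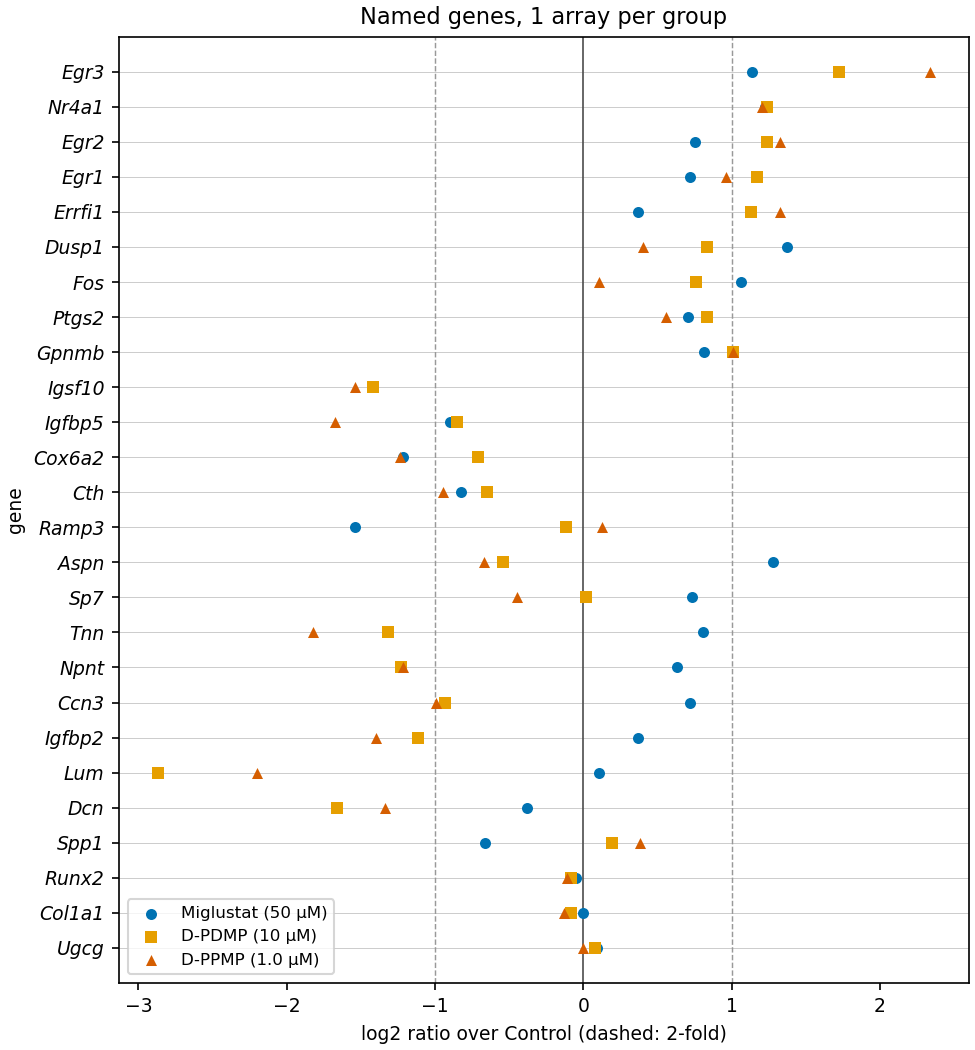
Log2 ratio over Control (horizontal axis) of 26 named genes, 1 array per group; circles are Miglustat, squares D-PDMP, triangles D-PPMP, and dashed lines mark 2-fold. Egr3 lies at 1.14, 1.72 and 2.34 and Lum at 0.10, -2.87 and -2.20.

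The inhibitors were also set against each other, at the different doses given. D-PDMP and D-PPMP share a phenyl and morpholino propanol core and differ in the acyl chain on the amide, decanoyl in the former and palmitoyl in the latter, whereas Miglustat is an N-butyl iminosugar. Matrix genes separated Miglustat from both others: Tnn was 4.34-fold higher with Miglustat than with D-PDMP and 6.16-fold higher than with D-PPMP, Lum 7.86-fold and 4.95-fold, Npnt 3.64-fold and 3.6-fold, and Aspn 3.54-fold and 3.86-fold. Ccn3 was 3.14-fold higher than with D-PDMP and Igfbp2 3.41-fold higher than with D-PPMP. Ramp3 was 2.68-fold and 3.18-fold lower with Miglustat, and the cardiac troponin Tnnt2 2.35-fold and 2.98-fold. Cbln1, a secreted synaptic organiser, and Aqp1, a water channel, were 2.19-fold and 2.16-fold lower than with D-PDMP, and Ngef 2.6-fold lower than with D-PPMP.

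Between D-PDMP and D-PPMP the log2 ratio was 0.82 for Igfbp5, 0.78 for the metalloprotease Pappa, which cleaves such binding proteins, 0.66 for Fos, 0.60 for Cdsn and 0.58 for Niban1. On the other side were Tlx2 at -1.14 on its brightest probe, the copper transporter Atp7b at -0.68, Egr3 at -0.61, Etv1 at -0.58 and Iqsec3 at -0.57. Counts of genes at least 2-fold apart were 26 for D-PDMP against D-PPMP, 104 for Miglustat against D-PDMP and 146 for Miglustat against D-PPMP, among 14553, 14408 and 14546 measured. With normexp they were 0, 19 and 40. The SD across genes of the log2 ratio was 0.190, 0.255 and 0.279, beside 0.217, 0.214 and 0.239 for Miglustat, D-PDMP and D-PPMP against Control. That D-PDMP and D-PPMP lay closer does not show that they act alike, since each was measured once and at its own dose.

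By list, the extracellular matrix median was 0.26 for Miglustat over D-PDMP, 0.45 for Miglustat over D-PPMP and 0.11 for D-PDMP over D-PPMP, each at percentile 100, with 37, 42 and 38 of 47 members above 0. Chondrocyte markers, matrix genes in part, were at 0.29 (99.67), 0.30 (99.93) and 0.04 in the same comparisons, the 0.30 being 0.19 with bounds. Of these 10 markers 5, 8 and 6 were above 0, so the 0.29 does not mark a shift of the whole list. The Wnt list was at 0.19, 0.24 and 0.03, the cytoskeleton list at 0.19, 0.19 and 0.00, and the unfolded protein and integrated stress response list at 0.08, 0.19 and 0.11. Cholesterol synthesis was at -0.19, -0.29 and -0.07, the interferon list at -0.16, -0.22 and 0.00, and oxidative stress and NRF2 targets at -0.16, -0.17 and -0.01. Immediate early genes were at -0.02, 0.02 and 0.10, so the former pair of medians lay inside the random range. Cell cycle genes were at 0.09 for Miglustat over D-PDMP while their mean was 0.00, with Prc1 and Mcm5 on opposite sides. Outside the middle 95% were 15, 11 and 6 of 28 lists.

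**Figure D3:**
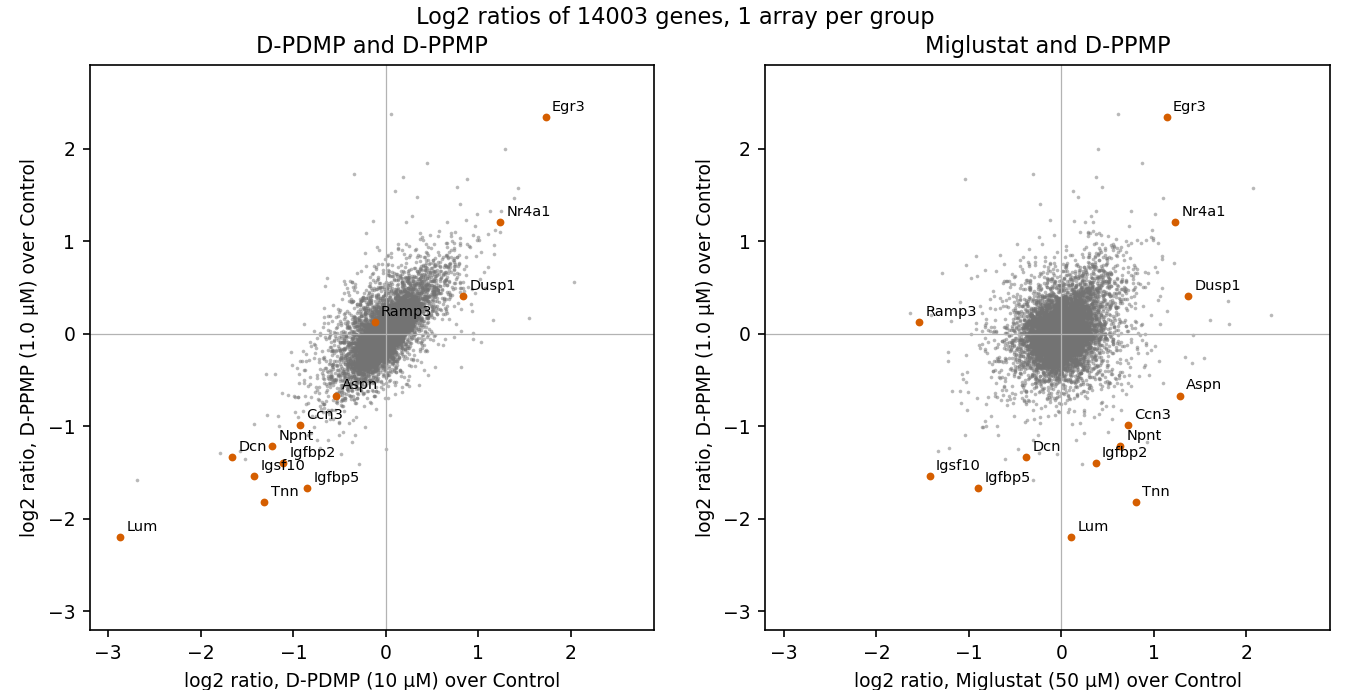
Log2 ratios over Control of 14003 genes well above background on all 4 arrays, D-PPMP (vertical axes) against D-PDMP (left) and against Miglustat (right), with 13 genes marked. The correlation across genes is 0.692 on the left and 0.271 on the right.

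Across the 14003 genes well above background on all 4 arrays, which are not independent replicates, the log2 ratios over Control correlated at r = 0.692 for D-PDMP and D-PPMP, 0.323 for Miglustat and D-PDMP and 0.271 for Miglustat and D-PPMP. Unchanged arrays sharing the Control gave r = 0.50 in each case, which equal and independent noise in every array gives by construction. The covariances were 0.0346, 0.0146 and 0.0137, beside simulated values of 0.0281, 0.0281 and 0.0280 with noise from all inhibitor pairs and 0.0158, 0.0158 and 0.0159 with noise from the D-PDMP and D-PPMP pair. Genes at least 2-fold higher and lower in both numbered 11 and 11, 6 and 3, and 5 and 4, such as Egr2 and Dcn for D-PDMP and D-PPMP. Unchanged arrays gave means of 9.43 and 9.23, 9.5 and 9.36, and 9.22 and 9.32 with the former noise, and 2.59 and 2.61, 2.57 and 2.47, and 2.43 and 2.54 with the latter. Independent lists of these sizes would share 0.0676 and 0.0386, 0.0456 and 0.0343, and 0.0891 and 0.0463 genes. A single Control array cannot be split, so part of any excess may come from the shared Control.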

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

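The genes on opposite sides and the gene values in this part were chosen after their values were seen, as were the test of array position, both tests on other probes for Miglustat against D-PPMP, and the other scalings of the unmatched probes.

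At least 1.5-fold from Control, 6 genes lay on one side with Miglustat and on the other with both D-PDMP and D-PPMP, a difference that was not tested. Higher with Miglustat were Tnn, whose log2 ratio exceeded the mean of the other inhibitors by 2.37, Npnt by 1.86, Ccn3 by 1.68 and Tafa2, a secreted signalling protein, by 1.36. Tnn, Npnt and Ccn3 encode proteins of the matrix or its surroundings. Tafa2 was at 0.64, -0.60 and -0.83. Lower with Miglustat were Megf10, an engulfment receptor, by -1.83 and Prl2c5, of the prolactin family, by -2.32. Their log2 ratios were -0.92, 0.98 and 0.84 for Megf10, and -1.04, 0.88 and 1.67 for Prl2c5. Unchanged arrays gave a mean of 0.18 such genes, and at most 1, in 100 simulations. Their noise was drawn separately for each array, without the closeness of D-PDMP and D-PPMP seen here. The simulations therefore cannot decide whether the pattern exceeds chance. By its mean over the 4 arrays only Ccn3 lay above the median level of genes, and only Tnn and Megf10 have another probe.

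Outside the gene comparisons, probes with no matched gene were at least 2-fold higher than in Control 28 times with Miglustat, 56 times with D-PDMP and 162 times with D-PPMP, of 10957, 10952 and 11067 well above background on both arrays. Lower were 13, 13 and 14, and 5 probes were higher and 1 lower with all 3 inhibitors. The 3 comparisons share the Control array, and no simulation was run for the unmatched probes. Under quantile normalization the counts higher and lower were 19 and 21, 21 and 33, and 53 and 43, and under cyclic loess 19 and 21, 25 and 27, and 50 and 36.

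The D-PDMP and D-PPMP arrays lay closer to each other (SD of log2 ratios 0.190) than to Miglustat (0.255 and 0.279), with Lum, Tnn, Npnt and Igfbp2 on the same side of Control in both. An intensity-dependent difference or noise of dim probes is argued against, since above the median level of genes and after cyclic loess the SD for D-PDMP against D-PPMP was 0.521 times the smaller of the other pairs' (0.0847 against 0.163 and 0.187). Position on the slide cannot be told apart from the groups: D-PDMP and D-PPMP were neighbours and Miglustat and D-PPMP lay 2 positions apart, although Miglustat and D-PDMP, also neighbours, differed with an SD 1.19 times that of Control and D-PDMP. Also open and untested is whether the closeness comes from the compounds, which share a core structure, from the doses, or from differences between single cultures. Replicate cultures at matched doses and varied positions would decide.

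Miglustat and D-PPMP differed at least 2-fold in 146 genes, in 40 with normexp, and in 42 when both levels had to be above the median of probes. Above that median on the brighter array, Tnn, Lum, Aspn, Npnt and Igfbp2 were highest, and Ramp3, Tnnt2 and Ngef were among the lowest. For the 34 genes with another probe well above background, aberrant single probes are argued against, since 33 of them, a share of 0.971, had the sign of the brightest probe, beside 3574 of 5362 among genes under 2-fold. Noise of dim probes stays open for the genes below the median level of genes: of the 34, 22 lay there and all had the same sign, a share of 1, but 33 of 34 left no room for another outcome. The other probes share the RNA of the same culture, so differences between single cultures stay open and were not tested. Against Control, 3, 5 and 7 called genes had such a probe with Miglustat, D-PDMP and D-PPMP, and 3, 3 and 6 kept the sign. In each of these comparisons 2 genes had it at least 1.5-fold apart on the same side.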

How the results depend on the processing

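No paired analysis was possible because each group has 1 array and no result comes from a test. The alternatives were chosen before the data were examined, except that normexp was planned on the mean spot signal, which the files lack. Under them, no correlation and no named gene at least 2-fold from Control changed sign. Nor did any list median against Control outside the middle 95% of random lists. List medians between inhibitors were not run under the alternatives. Medians against Control inside that range did in part, as given with the lists, and the side with more genes turned under some setting for each inhibitor. All 11 counts stayed within 1.5 times with the 75th percentile over detected probes, the authors' table, only probes well above background on all 4 arrays, and the condition of 2 times Agilent's error. In the order higher and lower with Miglustat, with D-PDMP and with D-PPMP, then apart for D-PDMP against D-PPMP, Miglustat against D-PDMP and Miglustat against D-PPMP, then higher and lower with all 3 inhibitors, the counts with normexp were 5, 4, 4, 2, 6, 8, 0, 19, 40, 1 and 0. With both levels above the median they were 8, 5, 4, 4, 4, 6, 1, 19, 42, 1 and 1, by construction among fewer genes. With no filter on dim probes they were 959, 553, 1250, 506, 1621, 364, 1544, 1613, 1751, 355 and 107, counting probes near background. Quantile normalization gave 14 higher with D-PDMP and 22 higher and 56 lower with D-PPMP. Cyclic loess gave 14 higher and 38 lower with D-PDMP and 21 higher and 48 lower with D-PPMP. The mean of a gene's probes gave 1 gene lower with all 3. The normexp offset of 50 was added to every signal, which shrinks the ratios of dim probes by construction. Median processed signals were 10.6, 11.95, 11.9 and 12.7 in Control, Miglustat, D-PDMP and D-PPMP. How much of the fall in the normexp counts comes from the offset was not tested. Nor was the cause tested for the counts under quantile and cyclic loess normalization. Correlations moved with normexp to 0.143 for Miglustat and D-PPMP, with no filter to 0.491, 0.492 and 0.575 for Miglustat and D-PDMP, Miglustat and D-PPMP, and D-PDMP and D-PPMP, and above the median level to 0.139 for Miglustat and D-PPMP and 0.805 for D-PDMP and D-PPMP. Of 46 values of named genes at least 2-fold from Control, 43 stayed so under quantile normalization, 44 under cyclic loess, 28 with normexp and 41 with the mean of probes, and all 46 kept their sign in each. Of 84 list medians against Control, 15, 22, 16 and 16 moved beyond the spread of random lists under these 4 settings, with no change of side for a median outside the middle 95% of random lists.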

Other observations

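The gene families in this part, the test of the Control culture and the resampling of other probes were chosen only after the result was seen.

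Gene families named by symbol stem, with some members already in the lists fixed beforehand, also had medians apart from Control. Differences between inhibitors were not tested. Families with at least 10 measured members numbered 150. Of these, 15, 17 and 13 had a median outside the middle 95% of random lists with Miglustat, D-PDMP and D-PPMP. By chance 7.5 would, if the members of a family varied independently of each other, which was not tested. The Mcm genes, most of them subunits of the replicative DNA helicase, had medians of -0.20 (percentile 0), 0.13 (99.99) and 0.13 (99.98), with the same signs under quantile, cyclic loess and normexp. Of 10 members 9 were below Control with Miglustat and 9 and 8 above it with D-PDMP and D-PPMP, and 6 also belong to the cell cycle list. Examples are Mcm5 at -0.31, 0.15 and 0.19, Mcm7 at -0.25, 0.13 and 0.17 and Mcm2 at -0.24, 0.13 and 0.21. The 10 include Mcm3ap, which encodes a protein associated with Mcm3 and not a subunit of the helicase. The frizzled genes, receptors for Wnt ligands, had medians of 0.04 (78.8), -0.25 (0.1) and -0.21 (0.27), and these signs held under the same scalings, though with normexp the D-PDMP and D-PPMP medians were -0.16 and -0.10. Fzd5 was at 0.28, -0.42 and -0.40 and Fzd8 at 0.22, -0.33 and -0.39, and the 10 include the noncoding Fzd10os and 4 members of the lists.

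Collagen genes, of which 30 were measured and 16 belong to the lists, had medians of 0.11 (percentile 100), -0.09 (0.03) and -0.13 (0), keeping these signs under the same scalings. With normexp, however, the Miglustat median was 0.03, with 17 of 30 above Control. Col11a1, a fibrillar collagen chain, was at 0.54, -0.36 and -0.43. Kinesin genes, motor proteins of microtubules, had medians of 0.08 (99.97), 0.00 and 0.04, the sign for D-PDMP turning under quantile and cyclic loess normalization. With normexp the Miglustat median was 0.01, with 17 genes above Control and 16 below. The 16 aldehyde dehydrogenase genes had medians of -0.05, -0.17 (0.01) and -0.10 (1.44), with Aldh1a3, which makes retinoic acid, at 0.07, -0.50 and -0.66. The 39 Cep genes, most of them of centrosomal proteins, had medians of 0.07 (99.83), 0.08 (99.89) and 0.06 (97.77). They include the opposite-strand transcript Cep83os and the Cep295-like Cep295nl, the latter at 0.50, 0.55 and 0.66. Aldehyde dehydrogenase and Cep medians kept their signs under these scalings, the Cep medians being 0.04, 0.04 and 0.02 with normexp and the D-PDMP aldehyde dehydrogenase median -0.09.

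Immediate early genes were higher than in Control with all 3 inhibitors, with list medians of 0.25, 0.36 and 0.20 and Nr4a1, Egr3, Egr2 and Egr1 as examples. A scaling or intensity-dependent difference is argued against by the smallest of the medians under quantile and cyclic loess normalization, 0.202. Over all other scalings run, the lowest list medians were 0.24, 0.25 and 0.17. Aberrant single probes stay open: the 8 other probes cover 8 of 29 members, 5, 7 and 6 of them lay above 0, and their smallest median, 0.212, had an SD of 0.224 on resampling. Whether the single Control culture differed for another reason, such as handling at harvest, cannot be told apart from an effect of the inhibitors: the Control array lay at -0.328 against the mean of the other 3, which both would give. A response to the inhibitors stays open too, and replicate cultures would decide.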
